A study of Homo sapiens with 8 samples.

How the data were processed

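RNA was compared between 2 groups of K562 cells that stably carried p42-C/EBPα-ER, 4 samples treated with 1 µM estradiol and 4 with ethanol vehicle, all for 6 h. Per the labels' protocols the cells grew in phenol red-free medium with 10% charcoal-stripped serum, and 200 ng of total RNA per sample was amplified, labelled with biotin and put on an array. The label of the vehicle group gives the ethanol as 1 µM, which was not taken further. Groups and replicate numbers came from the sample titles, which call the samples biological replicates, and nothing more on how the cultures were separated is given in the sources used here.

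The deposited values are log2 expression values that the authors made with RMA, per the submitters' processing notes, which give no version. RMA corrects the background of each array, brings all arrays to a common distribution and summarizes the probes of a probe set. Because of that step a change shared by most genes would be hidden, and changes of dim genes are understated. Chip definition, software and genome build are not given in the sources used here, so no coordinates are printed. The log2 scale was checked on the values, which ran from 1.92 to 14.39 with similar quartiles on every array. No detection calls were used here, so how far a dim gene lay above background is unknown.

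The table holds 54675 probe sets. In the platform annotation 41097 of them had 1 gene symbol, 1801 had several and 11777 had none listed, and 62 probe sets in all were controls of the array maker. Symbols were checked through the gene identifier in a RefSeq gene table for 41043 probe sets, and 0 changed. Only probe sets with 1 symbol were named. Of the 19775 genes, 10523 had several probe sets, and the probe set with the highest mean over all 8 arrays stood for the gene. Of 87 named genes 29 had 1 probe set, 28 had several that were all called in the same direction, 25 were called while at least 1 other probe set was not, and 0 had a probe set called the opposite way.

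Each gene was tested with limma 3.58.1 (lmFit and eBayes, no trend) in R 4.3.3, estradiol minus vehicle, two-sided, without a block or other covariate, on all 8 arrays and with no filter on dim genes. Adjusted p-values are Benjamini-Hochberg values over all genes, called below 0.05. Errors of log2 fold changes are the moderated standard errors of limma, and errors of levels are SDs over 4 arrays. P-values measure the spread between these samples. Gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 17 lists, and again with an estimated correlation and with fry. Figures were drawn with matplotlib 3.10.9.

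The groups, the test, the thresholds, the 17 lists, the processing alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap. From each list it took up to 4 called members with the largest change, or the member with the smallest p where none was called. CEBPA, ESR1, CSF3R, CEBPE, GATA1, MYC, E2F1, ID1, SOX4 and HBG1 were to be given whatever their values. HBG1 is not reported, because it shared its probe sets with another gene. No gene stood in more than 1 list.

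The tests were checked on simulated log2 values for the 19775 genes in 8 arrays, with 200 genes changed. Of 50 genes at each size, 22% were recovered at a log2 change of 0.25, 84% at 0.5 and 100% at 1 and at 2, and 3 of the 156 genes called had not been changed. The data gave 3538 calls, and with more calls the Benjamini-Hochberg adjustment lets larger p-values pass. The shares recovered at 0.25 and 0.5 may therefore understate those in the data. Of 60 simulated lists of 20 genes shifted by 0.2 on the log2 scale camera called 60, and of 280 unshifted lists it called 4. The simulated genes varied independently of each other, while the estimated correlation of the real lists reached 0.415 for G2 and mitosis genes. The 4 calls therefore do not measure how often camera falsely calls lists of correlated genes.

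Alternatives covered the replicate number as a block, 3 other scalings of the arrays, 2 filters on dim genes, the mean of all probe sets of a gene, every probe set on its own, a variance trend with a robust fit, array quality weights, each array left out in turn, a stricter adjusted p, other fold limits and the other set tests. All other splits of the 8 arrays into 4 and 4 were tested as well.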

Results

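Gene expression was measured in K562 cells, an established human line grown from a chronic myeloid leukaemia in blast crisis that carries erythroid features. The cells stably carried p42-C/EBPα, the full-length form of a transcription factor that drives granulocyte differentiation, fused to the oestrogen receptor (ER). Oestradiol moves such a fusion into the nucleus. Cultures received 1 µM estradiol or the ethanol vehicle for 6 h, with 4 arrays in each group, which the sample titles call biological replicates. Each array gave a log2 value for 54675 probe sets, and 19775 genes were compared. The medians of the arrays ran from 4.97 to 5.08 on the log2 scale, and the number of arrays limits the precision of every value. No group of cells without the fusion is named in the labels, so each difference below is that of estradiol in fusion-carrying cells.

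The comparison of estradiol with vehicle asked which transcripts differed after 6 h of estradiol in cells with the fusion. The place of the fusion within the cells was not measured here. Estradiol raised a signal annotated to the lipid receptor HCAR3, and raised the G-protein regulator RGS18, the phospholipid-binding protein ANXA1 and the early transcription factors FOS, ID1 and EGR1. It lowered the erythroid regulators HEMGN, GFI1B, LYL1, GATA1 and KLF1 and the growth regulator MYC. Of 18 measured regulators of the erythroid and progenitor state 11 fell and 4 rose, NFE2 and MYB among the rises. Camera did not call that list with an estimated correlation (adjusted p = 0.0678). Genes of ribosome assembly fell with MYC, while 29 of 48 genes of DNA replication and mitosis rose by smaller amounts, as lists that camera did not call with an estimated correlation (adjusted p = 0.103 and 0.230). Most granulocyte granule and receptor genes did not pass the test, with 16.7% and 19.4% called, near the 17.9% of all genes. In all, 3538 of the 19775 genes changed (limma, Benjamini-Hochberg adjusted p below 0.05), 1639 upward and 1899 downward, with median changes of 0.34 and −0.30 on the log2 scale. The excess of falls turned into an excess of rises with median centring of each array (54.5% of calls) and without vehicle replicate 1 (51.2%). At least a 1.5-fold change was reached by 385 rising and 191 falling genes, and at least a 2-fold change by 152 rising and 32 falling genes. The values of the groups did not overlap in 24.1% of all genes, where the chance for a gene taken alone is 2.86%. Genes on the same arrays can vary together, so this excess does not by itself exclude chance.

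**Figure D1:**
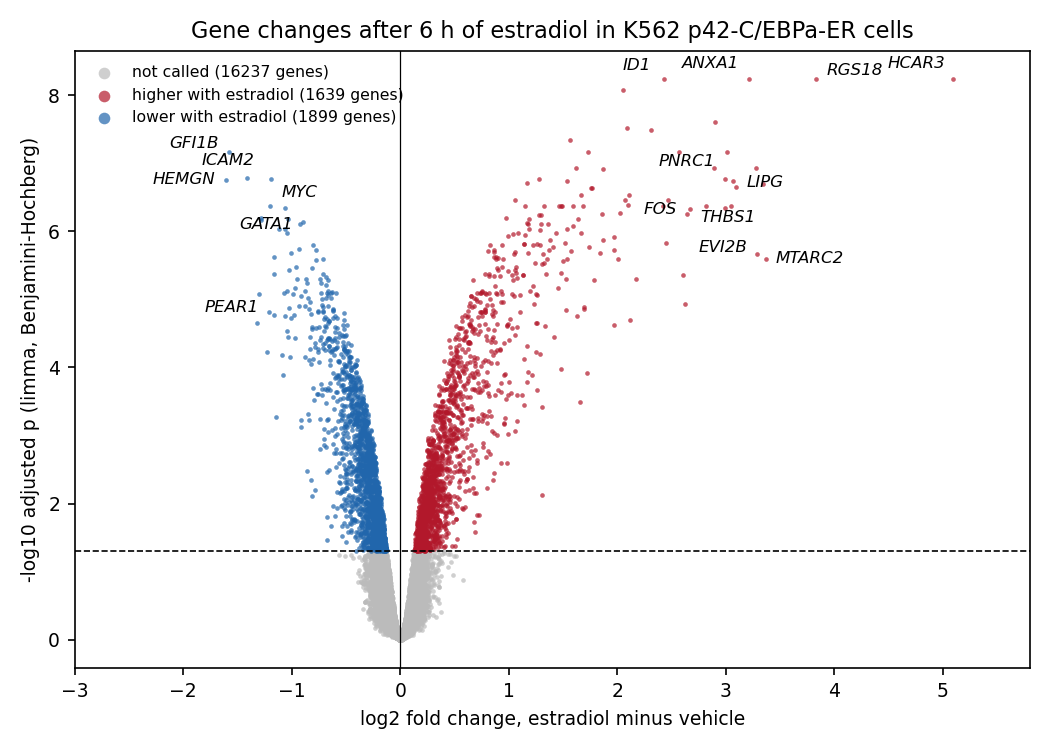
Log2 fold change (estradiol minus vehicle, x axis) against −log10 of the limma adjusted p (y axis) of 19775 genes, with 4 arrays per group. Points are genes, red for the 1639 called higher, blue for the 1899 called lower and grey for the rest, and the dashed line marks an adjusted p of 0.05. The largest rise was 5.09 (annotated to HCAR3) and the largest fall −1.61 (HEMGN).

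The genes of the fusion partners were not called at the probe sets measured. CEBPA had a log2 level of 6.35 ± 0.12 (SD, n = 4) with estradiol and 6.37 ± 0.06 with vehicle, a difference of −0.02 ± 0.07 (SE, limma adjusted p = 0.883). ESR1, the oestrogen receptor gene, stood at 8.75 ± 0.06 and 8.71 ± 0.09, a difference of 0.04 ± 0.06 (adjusted p = 0.699). Of its 9 probe sets, 5 had mean log2 levels of 7.27 to 8.73 and 4 had levels of 2.56 to 4.14, and 0 of the 9 were called. Whether any of these probe sets lies within the transgene is not given in the sources used here.

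The largest rise in signal was that annotated to HCAR3, a receptor for hydroxylated fatty acids, with a log2 level of 8.79 ± 0.06 (SD, n = 4) with estradiol and a difference of 5.09 ± 0.09 from vehicle (SE, adjusted p = 5.77e-09). HCAR3 has the near-identical neighbour HCAR2, so the signal cannot be assigned to either copy alone. The vehicle levels of HCAR3, TRDV3 (3.47) and LIPG (3.44) lay within or below the range of the lower quartiles of the arrays, 3.67 to 3.74, and those of RGS18, TNFSF10 (4.16), FOS (4.44), IL6R (4.65), C1orf115 (4.72), CXCL2 (3.79) and EVI2B (4.94) lay below the array medians. None of these levels was shown to be above background, so the folds and ranks of these rises are those of the signal. RGS18, a regulator of G-protein signalling in blood cells, was 14.2-fold higher, with log2 levels of 7.82 ± 0.10 (SD, n = 4) against 3.99 ± 0.05. The mitochondrial reductase MTARC2 rose 10.3-fold and the myeloid membrane protein EVI2B rose 9.79-fold. ANXA1, annexin A1, rose 9.29-fold to a log2 level of 12.21 ± 0.06. The endothelial lipase LIPG rose 8.55-fold, the interleukin-18 receptor chain IL18RAP 8.35-fold and the death ligand TNFSF10, also named TRAIL, 8.25-fold. KCNE3, a potassium channel subunit, rose 8.07-fold and PNRC1, a nuclear receptor coactivator, 7.97-fold. C1orf115 and TRDV3, a variable segment of the T-cell receptor delta locus, rose 10.2-fold and 9.68-fold, each on 1 of its 2 probe sets, while the other showed 0.06 and −0.02 on the log2 scale.

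The genes with the largest falls were HEMGN, an erythroid nuclear protein, at 3.05-fold lower (log2 fold change −1.61 ± 0.05 SE, adjusted p = 1.75e-07), and GFI1B, a repressor needed for red cell and platelet formation, at 2.99-fold lower (−1.58 ± 0.04, adjusted p = 6.85e-08). The adhesion molecule ICAM2 was 2.67-fold lower, the caveolar protein CAVIN2 2.49-fold lower and C11orf21 2.46-fold lower. ENDOD1, CHST2, UBASH3A and the platelet receptor PEAR1 fell by 1.28, 1.28, 1.23 and 1.21 on the log2 scale. ARHGAP22 was 2.30-fold lower on 1 of its 4 probe sets, with the other 3 between −0.01 and 0.17. MYC fell from a log2 level of 12.10 ± 0.02 (SD, n = 4) to 10.91 ± 0.02, 2.28-fold, and CAPRIN2 was 2.25-fold lower. With the mean of their probe sets C11orf21, CHST2 and CAPRIN2 changed by −0.81, −0.77 and −0.73.

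**Figure D2:**
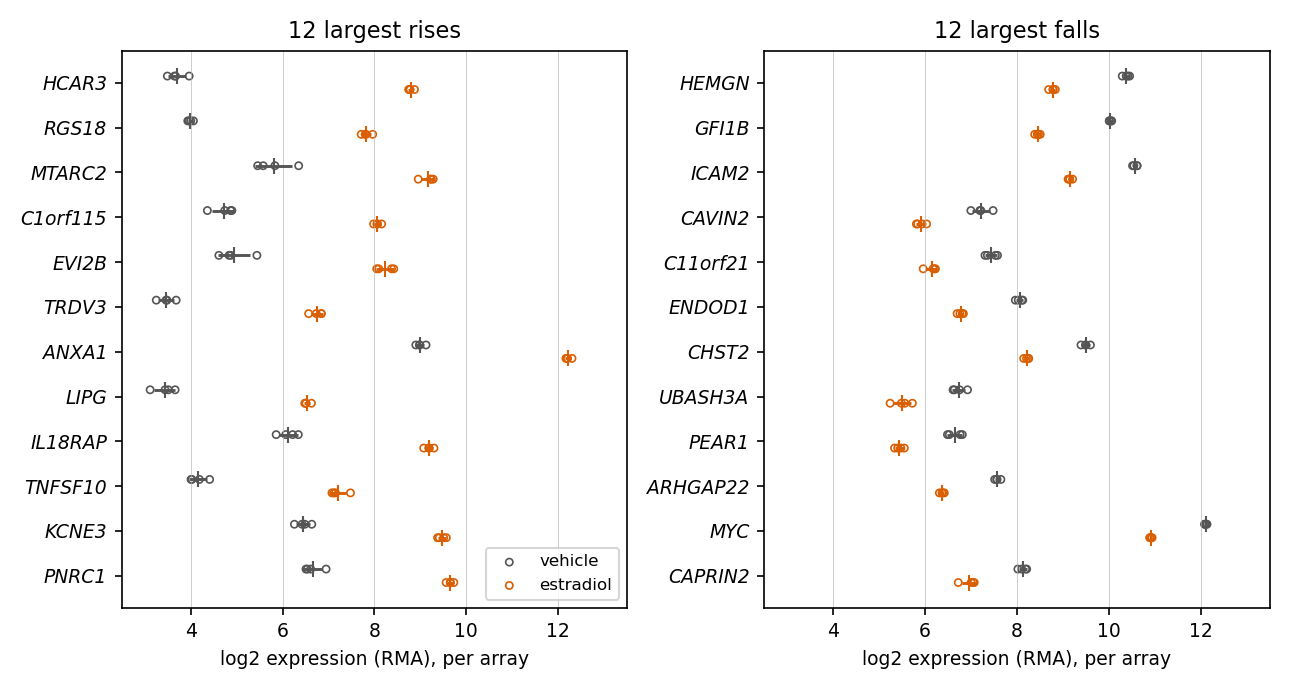
Log2 expression per array (x axis, RMA values) of the 12 genes with the largest rises (left) and the 12 with the largest falls (right). Open circles are arrays, 4 with vehicle (grey) and 4 with estradiol (orange), and each short bar with its line gives the mean and SD. The groups did not overlap in any of the 24 genes, and ANXA1 reached the highest mean with estradiol among the rises shown, 12.21.

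Of 404 genes in 17 lists, 369 were measured and the other 35 were not analysed here. Among them 79 rose and 63 fell. List members outside the rule for named genes were named after their values had been seen. KLF1, SPI1, RRP9, CDKN1A, CDKN1B, HBE1, HBD and MPO are among them.

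Regulators of the erythroid and progenitor state shifted downward as a list in camera with a preset correlation (adjusted p = 0.00103) and not with an estimated correlation (adjusted p = 0.0678). Of 18 measured members 11 fell, 4 rose and 3 were not called (12 and 4 adjusted over the list alone, with SOX4 added to the falls). GFI1B led the falls, followed by LYL1 at 2.09-fold lower, GATA1, the master regulator of red cell genes, at 1.86-fold lower (−0.89 ± 0.04 SE) and the erythroid activator KLF1 at −0.71 ± 0.04. NFE2 (1.82-fold), MYB (0.68 ± 0.04), HHEX (0.53 ± 0.05) and ETV6 (0.46 ± 0.09) rose. SOX4, a progenitor factor, differed by −0.20 ± 0.06 without passing the test over all genes (adjusted p = 0.0580, or 0.0470 without vehicle replicate 4), while 1 of its 6 probe sets was called lower among all probe sets (−0.44, adjusted p = 0.0336). The list median was −0.28.

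Genes of red cell structure and haem synthesis also shifted downward in camera with a preset correlation (adjusted p = 2.45e-05) and not with an estimated correlation (adjusted p = 0.0531). Of 24 measured members 13 fell, 1 rose (ERMAP, 0.27 ± 0.06) and 10 were not called, with 14 falls adjusted over the list alone. The mitochondrial iron importer SLC25A37 fell 2.10-fold (log2 changes of −1.28 to −0.31 over its 10 probe sets), the blood group protease KEL 1.43-fold and the cytoskeletal anchor ANK1 1.38-fold. SLC4A1, the anion exchanger band 3, fell by 0.30 on the log2 scale on 1 of its 2 probe sets. Among the globins, HBE1 fell by 0.17 and HBD by 0.16, while HBB differed by −0.09 ± 0.07 and HBZ by −0.04 ± 0.04 without passing the test. The list median was −0.18.

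Myeloid and immediate early transcription factors shifted upward as a list in camera with a preset correlation and in fry, and not in camera with an estimated correlation. Of 19 measured members 9 rose, 9 were not called and 1 fell (JUNB, −0.38 ± 0.05), with 9 rises and 3 falls adjusted over the list alone, where CEBPD and VDR were added to the falls. FOS rose 6.26-fold in signal from a dim vehicle level, ID1, an inhibitor of basic helix-loop-helix factors, 5.38-fold (log2 fold change 2.43 ± 0.04 SE, adjusted p = 5.77e-09), ID2 3.21-fold and EGR1 2.38-fold. SPI1, the myeloid factor PU.1, rose by 0.39 ± 0.05 and CEBPE, a granulocyte factor, by 0.41 ± 0.08 (1.33-fold, adjusted p = 0.00783). CEBPB differed by 0.09 ± 0.04 without passing the test. The list median was 0.16 (camera adjusted p = 2.36e-06, adjusted p = 0.0678 with an estimated correlation).

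Most granulocyte granule genes did not pass the test, and the share called, 16.7%, was near the 17.9% of all genes. The list mean ran from 4.55 to 4.66 over the arrays, below the array medians of 4.97 to 5.08, so changes of its dim members may be understated. Of 24 measured members 3 rose, the haptoglobin gene HP (0.60 ± 0.12), the protease inhibitor SERPINB1 (0.36 ± 0.05) and lysozyme, LYZ (0.25 ± 0.07), and 1 fell, neutrophil elastase, ELANE (−0.23 ± 0.07), with 3 and 1 adjusted over the list alone. The ELANE levels, 4.29 with estradiol and 4.52 with vehicle, were not shown to be above background. MPO, the myeloperoxidase gene, differed by −0.02 ± 0.08. Camera did not call the list (median 0.02, adjusted p = 0.179, adjusted p = 0.241 with an estimated correlation), while fry called it upward (adjusted p = 0.0340). The LYZ call was lost without estradiol replicate 1 or 2 or vehicle replicate 2, 3 or 4, at adjusted p from 0.0574 to 0.0750. ELANE lost its call in every fit without 1 array except that without estradiol replicate 3, at adjusted p from 0.0549 to 0.109, and under all 3 other scalings of the arrays, at adjusted p from 0.0593 to 0.0925.

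Receptors and adaptors of granulocytes and monocytes moved both ways. Of 31 measured members 3 rose, IL6R 3.15-fold, the Fc receptor FCGR2A 2.07-fold and FCER1G by 0.31 ± 0.06, and 3 fell, TNFRSF1B (−0.50 ± 0.06), FPR2 (−0.34 ± 0.05) and TYROBP (−0.28 ± 0.06). Adjusted over the list alone there were 3 rises and 4 falls, with CSF2RB added to the falls. CSF3R, the receptor for granulocyte colony-stimulating factor, stood at 5.42 ± 0.08 and 5.35 ± 0.20 (SD, n = 4), a difference of 0.08 ± 0.10 (SE, adjusted p = 0.689). With the mean of their probe sets FCGR2A and FPR2 changed by 0.57 and −0.22. FCGR2A was 7.46 in vehicle replicate 1 against 7.19 to 7.20 in the other 3 vehicle arrays. The list had a median of −0.04 and a mean of 0.04, and camera ranked it downward at adjusted p = 0.949.

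Among 17 measured genes of eosinophils, basophils and mast cells 3 rose and 1 fell, both over all genes and adjusted over the list alone. MS4A3, a membrane protein of granulocyte precursors, rose 4.19-fold (log2 fold change 2.07 ± 0.07 SE), the leukotriene enzyme ALOX5 by 0.69 ± 0.18 and the eosinophil major basic protein gene PRG2 by 0.36 ± 0.06. KIT, the stem cell factor receptor, fell by 0.37. Camera did not call the list (adjusted p = 0.329), while fry called it upward (adjusted p = 0.00138). The ALOX5 call rested on 1 of 4 probe sets and was lost without estradiol replicate 2 or 3 or vehicle replicate 3, at adjusted p from 0.0645 to 0.0763.

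MYC and genes of ribosome biogenesis shifted downward as a list in camera with a preset and an estimated correlation. Of 21 measured members 16 fell, 2 rose and 3 were not called, with 18 falls adjusted over the list alone. After MYC, the ribosome assembly factor NOP16 fell 1.58-fold, the RNA polymerase I subunit POLR1B 1.49-fold and RRP9 by 0.48 on the log2 scale. Other probe sets of NOP16 and POLR1B reached 0.01 and 0.05, and with the mean of all probe sets the changes were −0.32 and −0.35. MAX, the dimerization partner of MYC, rose 1.49-fold (0.44 to 0.57 on the log2 scale over its 5 probe sets), and PNO1 rose by 0.22 ± 0.04. The nucleolar protein NPM1 differed by 0.01 ± 0.04. The list median was −0.27 (camera adjusted p = 4.48e-08), and this was the single list also called with an estimated correlation (adjusted p = 0.0422).

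In the lists of cell division genes 29 of 48 measured members rose, and camera called both lists with a preset correlation (adjusted p = 1.08e-11 and 1.15e-07) and neither with an estimated correlation (adjusted p = 0.103 and 0.230). In the list of E2F and S phase genes 16 of 26 measured members rose and 0 fell, with 20 rises adjusted over the list alone. The cyclin CCNE2 rose 1.73-fold, E2F2 1.41-fold and the replication licensing factors CDT1 and CDC6 1.29-fold each, while E2F1 differed by 0.16 ± 0.06 (SE, adjusted p = 0.104). In the list of G2 and mitosis genes 13 of 22 rose and 0 fell, with 15 rises adjusted over the list alone. The mitotic kinesins KIF11 and KIF23 rose by 0.43 ± 0.06 and 0.34 ± 0.07, the spindle kinase TTK by 0.39 ± 0.06 and NUSAP1 by 0.36 ± 0.05. KIF23 was called on 1 of 2 probe sets, and with the mean of both its change was 0.16 (adjusted p = 0.183). With the mean of their probe sets E2F2 and CDT1 rose by 0.32 and 0.23. List medians were 0.17 and 0.19. The mean of the 48 genes of both lists was 9.98 in vehicle replicate 2 and 10.04 to 10.06 in the other vehicle arrays, against 10.20 to 10.25 with estradiol. Without vehicle replicate 2 the rises numbered 13 and 13.

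Genes tied to cell cycle exit moved in both directions. Of 17 measured members 6 rose and 4 fell (7 and 5 adjusted over the list alone, with RBL2 and MXI1 added). Cyclin G2, CCNG2, rose 3.24-fold, the antiproliferative gene TOB1 3.17-fold and KLF2 2.33-fold, and the cyclin-dependent kinase inhibitors CDKN1A and CDKN1B rose by 0.72 ± 0.08 and 0.46 ± 0.05. Another inhibitor of that family, CDKN1C, fell 1.99-fold, with BTG1 (−0.44 ± 0.05), TOB2 (−0.39 ± 0.07) and CDKN2D (−0.36 ± 0.09). Other probe sets of KLF2 and CCNG2 reached down to −0.07 and −0.08, and with the mean of all probe sets the changes were 0.58 and 0.96. Camera did not call the list (median 0.00, adjusted p = 0.214), while fry called it upward (adjusted p = 0.00745).

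Stress and amino acid response genes also split. Of 20 measured members 8 rose and 4 fell, both over all genes and adjusted over the list alone. ATF3 rose 2.87-fold, TRIB3 2.25-fold, DDIT3, the factor CHOP, 1.74-fold and DDIT4 1.73-fold. The probe sets of ATF3 ran from −0.02 to 1.52, with 0.66 for their mean. The falls were SLC3A2 (−0.30 ± 0.04), HERPUD1 (−0.25 ± 0.06), PSAT1 (−0.20 ± 0.05) and ATF4 (−0.18 ± 0.04). The median was −0.01 while the mean was 0.20 and camera ranked the list upward at adjusted p = 0.0923, or adjusted p = 0.0360 with the mean of all probe sets of a gene, and fry called it upward at adjusted p = 0.00200.

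NF-kB and inflammatory cytokine genes shifted upward on a margin that depended on single arrays. Of 22 measured members 6 rose and 2 fell (7 and 2 adjusted over the list alone, with IL1A added). IER3 rose 3.34-fold, the chemokine CXCL2 1.63-fold on 1 of 3 probe sets, the inhibitor NFKBIA 1.54-fold and TNFAIP3 1.33-fold, while NFKB1 (−0.39 ± 0.05) and ICAM1 (−0.36 ± 0.06) fell. The other probe set of NFKBIA showed −0.14, and the mean of both 0.24. The median was 0.06 and camera gave adjusted p = 0.0401, against adjusted p = 0.110 with an estimated correlation. The list call was lost without estradiol replicate 3 (adjusted p = 0.0569), vehicle replicate 1 (0.0581) or vehicle replicate 4 (0.0557), and that of TNFAIP3 without estradiol replicate 2, 3 or 4 (0.0541 to 0.0660).

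Megakaryocyte and platelet genes, 20 of them measured, were called as a list by neither camera nor fry. THBS1, the platelet protein thrombospondin 1, rose 6.37-fold (0.97 to 2.71 on the log2 scale over its 7 probe sets), the proteoglycan SRGN 3.24-fold and RAB27B 1.83-fold. TUBB1, the platelet beta tubulin, fell 2.03-fold, MEIS1 by 0.54 and GP6 by 0.34 on the log2 scale, and adjusted over the list alone there were 3 rises and 4 falls with PPBP added. With the mean of their probe sets SRGN, RAB27B and TUBB1 changed by 0.99, 0.46 and −0.67. The median was −0.05, the mean 0.13, and camera ranked the list upward at adjusted p = 0.949. The list mean was 5.89 in vehicle replicate 2 and 5.98 to 5.99 in the other vehicle arrays.

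Oestrogen response genes known from breast cells were called as a list by neither camera nor fry. Of 21 measured members 2 rose, ADCY9 (0.46 ± 0.05, 1 of 3 probe sets) and KCNK5 (0.28 ± 0.05), and 3 fell, NRIP1 (−0.43 ± 0.06), SIAH2 (−0.33 ± 0.05) and IGFBP4 (−0.25 ± 0.05), with 2 and 3 adjusted over the list alone. The classical oestrogen targets TFF1, GREB1 and PGR, named after their values were seen, differed by 0.02 ± 0.07, −0.11 ± 0.07 and 0.16 ± 0.06 without passing the test. Camera gave adjusted p = 0.561 for the list.

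Interferon-stimulated genes were called as a list by neither camera nor fry (23 measured, camera adjusted p = 0.606). RSAD2 alone fell, by 0.52 on the log2 scale, while adjusted over the list alone 0 members passed. The RSAD2 call was lost without estradiol replicate 2 or 4 or vehicle replicate 1, 3 or 4, at adjusted p from 0.0523 to 0.0571. In the lists of fat and liver genes (23 measured) and lymphoid genes (21 measured), which served as markers of other lineages, 0 members were called in limma, also when adjusted over the list alone. The smallest p in each belonged to FGB (−0.23 ± 0.09, adjusted p = 0.113, or 0.0369 without vehicle replicate 2) and NKG7 (−0.15 ± 0.06, adjusted p = 0.141). Camera gave adjusted p = 0.918 and 0.606.

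**Figure D3:**
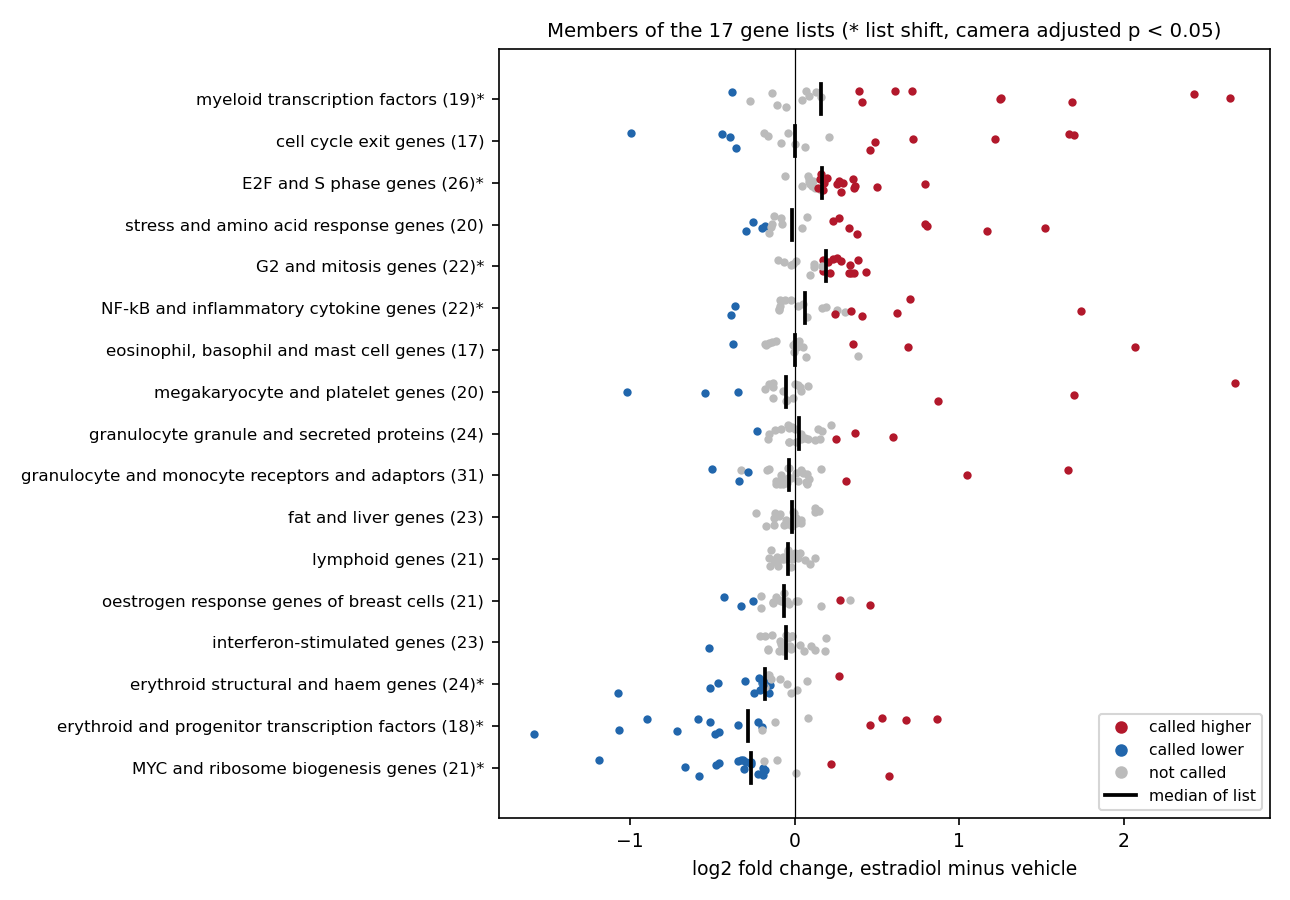
Log2 fold change (estradiol minus vehicle, x axis) of the 369 measured members of the 17 lists, ordered by list mean, with the number of members in parentheses. Points are genes, red for called higher, blue for called lower and grey for not called, and black bars are list medians. An asterisk marks the 7 lists called by camera with a preset correlation, with medians from −0.28 for the erythroid and progenitor transcription factors to 0.19 for G2 and mitosis genes.

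Camera called 7 of the 17 lists, 4 upward and 3 downward, and 1 of them with an estimated correlation. That version gave larger p-values even where the estimate was below the preset 0.01. For the NF-kB list, at −0.012, the unadjusted camera p was 0.0387 against 0.0165. The estimate was 0.020 for both erythroid lists, against 0.285 for S phase and 0.415 for mitosis genes. A call lost with an estimated correlation thus does not by itself show that the genes of a list varied together. The fry test, which asks only whether the genes of a list move on balance in a direction, called 11, these 7 and the lists of granule, eosinophil and basophil, cell cycle exit and stress genes.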

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

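Tests of expression level and of vehicle replicate 2 on the cell cycle and MYC lists, of the spike controls and of AKR1C cross-hybridization were chosen only after the result was seen. The grouping by gene symbol and the NFE2L2 list were drawn up after the gene values were seen, though before their own tests.

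Genes of S phase and mitosis rose while MYC and ribosome biogenesis genes fell in the same arrays, though with an estimated correlation camera called the MYC list alone (adjusted p = 0.103 and 0.230 for S phase and mitosis). A trend of fold change with expression level is argued against, because the medians of 3 of the 3 lists lay outside the central 95% of 10000 random lists matched on mean expression. Vehicle replicate 2, which stood apart, is argued against too, since without it the medians kept at least 0.909 of their size. Chance differences in the cell cycle state of the cultures stay open, since the mean of the 48 division genes, 10.23 ± 0.02 with estradiol and 10.03 ± 0.04 with vehicle (SD, n = 4), did not overlap between groups but reached an exact two-sided permutation p of 0.0286, the smallest that 70 arrangements can give and too large for lists picked from 17. Also open is that the fusion, or estradiol itself, may lower MYC directly, which no sample here tests.

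Rises of at least 2-fold outnumbered falls by 152 to 32, or by 110 to 14 with the mean of all probe sets of a gene. The floor of dim probe sets is argued against as the whole cause, since among genes in the top 25% of mean level the ratio of rises to falls was 5.44 (49 against 9), and 2.36 in the top 25% of vehicle level. A shift from between-array normalization is argued against by the hybridization spikes. Every log2 fold change would have to move by 0.282 to make the numbers equal, while no estradiol array exceeded any vehicle array by more than 0.168 in the mean of these spikes. For the bacterial RNA spikes that largest excess was 0.237. Their mean ran from 7.35 in estradiol replicate 1 to 7.85 in vehicle replicate 1, a spread too wide to decide. Neither kind of spike tracks the amount of RNA per cell. A candidate explanation that stays open and untested is that 6 h may be too short for stable transcripts to decay.

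Genes whose symbols begin with AKR, the aldo-keto reductases, were higher as a family of 10 (camera adjusted p = 0.0285 over 348 families, but 0.986 with an estimated correlation), with AKR1C1 at 1.28 ± 0.04, AKR1C2 at 1.30 ± 0.05, AKR1C3 at 0.37 ± 0.11 and AKR1C4 at 0.35 ± 0.10 called. The AKR1C4 levels, 3.38 with estradiol and 3.03 with vehicle, lay below the lower quartile of every array and were not shown to be above background. The family result rested mainly on the AKR1C genes. The other AKR genes did not rise as a group, with 0 of 5 called and an unadjusted camera p of 0.544. Adjusted over the family alone there were 5 rises and 0 falls, with AKR7A2 (0.16 ± 0.05) added to the rises. Outside AKR1C the largest change was a fall without a call, AKR1E2 at −0.18 ± 0.08. Cross-hybridization among the near-identical AKR1C copies may play a part. This test cannot tell it from a true rise of several AKR1C genes, and no probe sequences were checked. An antioxidant response through NFE2L2 may also be at work, since of 20 measured targets without AKR genes 7 rose, 2 fell and 11 were not called, with an unadjusted camera p of 0.00112, or 0.0268 with an estimated correlation (0.00280 and 0.0669 adjusted over 5 sets of genes). Against a uniform response, SRXN1 fell by 0.41 and NQO1 differed by 0.03 ± 0.04. Both explanations stay open.

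Among the 35 splits of the 8 arrays into 4 and 4, 1 split, the real one, gave as many as 3538 changed genes and the highest other gave 0 in limma. For changes of at least 1.5-fold 1 split, the real one, gave 576, with 0 as the highest other. Every other split put arrays of both treatments on each side, so the treatment difference widened the spread within its sides. The splits therefore cannot show how many calls chance alone would give, and chance is not excluded by them. For the 7 lists that shifted chance cannot be excluded by their number, since 2 of the 35 splits gave as many and the highest other gave 9, the split that put vehicle replicate 2 with estradiol replicates 1, 2 and 3. The 18 splits with equal numbers of each group on each side gave 0 lists, and the 16 with 3 arrays of a group and 1 of the other, which carry part of the treatment difference, gave 3 to 9. All 7 called lists had their smallest camera p in the real split, by which they had been picked.

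Single arrays stood far from the others of their group in 12 of 222 group values checked, where chance gives about 5%. The gap of the outlying array over the range of the group was 0.830 for LIPG and 0.880 for NFE2 in estradiol replicate 2, 0.913 for E2F2 in estradiol replicate 3 and 0.879 for KIT in estradiol replicate 1. It was 0.951 for FCGR2A in vehicle replicate 1, 0.837 for KIF23 and 0.871 for FGB in vehicle replicate 2, and 0.882 for HP and 0.922 for ELANE in vehicle replicate 3. The mean of the megakaryocyte list gave 0.885 in vehicle replicate 2. Among array controls it was 0.901 for the mean of the bacterial RNA spikes in estradiol replicate 1, at 7.35 against 7.71 to 7.75, and 0.889 for that of the hybridization spikes in estradiol replicate 2, at 9.90 against 9.78 to 9.79.

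Outside the named genes, 286 of 11721 probe sets with no gene listed were called in limma (2.44%, 84 of them lower). Of 1801 probe sets with several genes listed 307 were called, 139 higher and 168 lower.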

How the results depend on the processing

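Every alternative here was fixed beforehand. Without 1 array at a time, the count of genes that changed with estradiol ran from 2732 to 3551, that of genes that changed at least 1.5-fold with estradiol from 567 to 592, and that of gene lists that shifted with estradiol from 6 to 7. Testing every probe set under its own ID gave 5669 calls, 1254 of them at least 1.5-fold, out of 54675. An adjusted p below 0.01 left 2179 genes and a minimum fold of 2 left 184, both by construction. Camera with an estimated correlation called 1 list and fry 11. Under the other settings 2598 to 4370 genes changed, 433 to 752 at least 1.5-fold, and 6 to 7 lists shifted. The share of calls that were rises was 54.5% with median centring, 41.6% with quantile normalization and 48.6% with cyclic loess, against 46.3% as reported, and these 3 scalings placed the median of all genes between −0.02 and 0.00.

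No sign was seen that the replicate numbers paired the arrays, which does not show that the cultures were unpaired. Deviations of same-numbered arrays from their group means correlated at −0.05, −0.21, 0.09 and 0.11 across genes, and 2 of 8 samples correlated best with their own number. With the replicate block 2598 genes that changed with estradiol were found, 2534 of them among the 3538, with 571 genes that changed at least 1.5-fold with estradiol and 7 lists, and ALOX5, SLC4A1 and KIT were not called.

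Of the 87 named genes 75 were on the same side of the threshold in every fit that held them. Beside the losses given with each gene, the mean of all probe sets ended the calls of CXCL2 (adjusted p = 0.0737), TNFAIP3 (0.0612), KIF23 and SLC4A1 (0.120), and a variance trend that of ELANE (0.0974). E2F1 was called with cyclic loess (0.0317) and without the dimmer genes (0.0355), as was SOX4 without the dimmest 25% (0.0377) or 50% (0.0179). The NF-kB list also lost its call without dim genes (adjusted p = 0.179 and 0.323), with the mean of all probe sets (0.0893) and with a variance trend (0.0583). The mean of all probe sets also reduced by over 1.5 times, without ending the call, the changes of C1orf115 (to 1.71), TRDV3 (1.63), ALOX5 (0.18), ADCY9 (0.22) and ARHGAP22 (−0.26), beside those given with each gene. No called gene or list turned its direction. The cause of these changes was not tested.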

Other observations

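The genes, families and the fatty acid list in this part were chosen after the values had been seen. Beyond the rule for named genes, estradiol raised several regulators and secreted factors by large amounts. The growth factor EREG rose 7.95-fold, the hypoxia-related factor EPAS1 7.49-fold (log2 fold change 2.90 ± 0.06 SE), the zinc finger factor ZBTB16 7.04-fold and the soluble pattern receptor PTX3 6.09-fold. GBP2 rose 5.54-fold, IL18R1, the partner chain of IL18RAP, 4.34-fold, the pseudokinase TRIB1 4.14-fold and arginase 1, ARG1, 3.91-fold. The vehicle levels of PTX3 (3.26) and ARG1 (4.06) were not shown to be above background, so these folds are those of the signal.

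Of 348 groups of at least 8 genes that share the start of their symbol, camera called 7, with 5 lower and 2 higher, and 0 with an estimated correlation. The lower groups were UTP (8 of 10 fell, median −0.30) and RRP (7 of 8 fell, median −0.32), both of ribosomal RNA processing, NOL (5 of 10, median −0.17), the POLR polymerase subunits (12 of 32 fell and 1 rose, median −0.10) and the DDX helicases (12 of 39 fell, median −0.13). Some of these genes also stand in the list of MYC and ribosome biogenesis genes, among them UTP20, RRP9, RRP12, POLR1B and DDX21. The higher groups were AKR and the RAB GTPases, of which 21 of 71 rose and 7 fell (median 0.03). No direction turned under the 3 other scalings.

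HCAR3 (by its annotation), LIPG, ACSL1 (2.89 ± 0.08), PLIN2 (2.56 ± 0.07) and GPAT3 (2.09 ± 0.05), all tied to fatty acid sensing, release, activation or storage, were among the genes that rose most. A rise of such genes as a group was tested on a list of 34 genes of fatty acid uptake, activation and storage. With these 5 the list was higher (unadjusted camera p = 0.0482, 0.191 with an estimated correlation), with 8 rises and 3 falls. The 29 further genes gave an unadjusted camera p of 0.471 without these 5, with a median of −0.07, 3 rises and 3 falls, and fry ranked them downward (unadjusted p = 0.0191). The rise of the list thus rested on the genes that had prompted it, and a rise of part of the group is not excluded. The transporter SLC27A6 (1.17 ± 0.10), ACSL4 (0.35 ± 0.07) and PLIN3 (0.22 ± 0.04) rose, while SLC27A4 (−0.38 ± 0.05), HILPDA (−0.30 ± 0.05) and FABP5 (−0.23 ± 0.04) fell.

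The arrays separated by treatment along the first principal component, which held 57.2% of the variance. Vehicle replicate 2 lay apart on the next component (15.7%) and received the smallest array weight, 0.344. Its root mean square difference from the mean of the rest of its group was 0.205 on the log2 scale. The same measure was 0.112 to 0.172 for the other arrays.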
